A study of Mus musculus with 2 samples.

How the data were processed

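The data were polyA-selected RNA-seq profiles of the mouse cell line G1E-ER4, from 2 libraries of 1 group, kept for 7 hours in estradiol at 10 nM. The labels numbered the libraries as biological replicates 1 and 2. Both cited the same biological sample record, so the spread between them may be technical rather than a spread between separate cultures. The labels gave no untreated sample and no other time point, so no comparison between groups was made. With 2 libraries the smallest two-sided exact sign-flip p is 0.5, and no such test was run.

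For each library, the authors deposited a table of genes and a table of transcripts. Per the notes that accompany the files, the values were derived from alignments to the transcriptome, on genome build mm10 with the GENCODE M4 annotation. The aligner and the quantifier were not given in the sources used here. The deposited expected counts, and the posterior mean counts beside them, were estimates of fragments per gene or transcript that need not be whole and were not normalized. The deposited TPM values were scaled by effective length to the same total in each library, and a posterior mean TPM stood beside them. The deposited FPKM values were read but entered no result. Percent values in the authors' transcript tables gave each transcript's share of its gene. The shares reported here were computed anew from transcript TPM.

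Gene names, positions, types and GC content came from GENCODE M21 on GRCm38, which is the same assembly as mm10 with a later annotation. Of 43346 gene rows, 42462 matched by identifier without its version, and the other 884 held 0.248% and 0.257% of the counts of replicates 1 and 2. Of 103639 transcript rows, 101510 matched. A further 26248 rows with numbers for names held 2 and 0 counts, and 97 spike-in rows held 0 counts in both libraries. The gene tables covered 21474 protein-coding genes.

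A gene was called detected at a TPM of at least 1 in both libraries. Agreement between the libraries was measured by Pearson's r and Spearman's rho of log2 TPM with a pseudocount of 1 across protein-coding genes, which are not independent replicates. The biological coefficient of variation was the square root of edgeR's common dispersion on rounded expected counts with TMM scaling, for genes with at least 10 counts in both libraries. Each gene with at least 10 counts over both libraries was tested with an exact two-sided binomial test against the ratio of TMM-scaled library sizes, with Benjamini-Hochberg adjustment. A gene was called different at an adjusted p under 0.05 and a fold of at least 2. That test compares these 2 libraries, not conditions, and takes counting noise as the only error. Log2 ratios between the libraries carried a prior count of 0.5.

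There were 24 fixed gene lists, holding 273 matched genes. Hbb-b1, Hbb-b2, Ahsp and Rn7sl1 were on the lists and were not analysed here. The median TPM of each list was placed among 10000 random lists of the same size drawn from protein-coding genes. The median log2 ratio of each list, over members with at least 10 counts, was placed among 10000 random lists matched on expression in 20 bins. Both percentiles describe these libraries and are not p-values. The lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 3 most abundant members of each list, up to 4 detected markers of each other cell type, and 19 genes chosen for their place in erythroid cells. It also named the 10 most abundant nuclear protein-coding genes, the 10 genes with the largest log2 ratio at a mean TPM of at least 5, and the genes of the isoform comparison. Some genes that the rule names are not reported here. Genes named outside this rule were Kdm5d, Uty and Xist, which are on the lists, and those said in the closing section to have been noticed or singled out after the data were examined.

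Errors are the SD over the 2 libraries (n = 2). Where a count was 0, the limit given is that of 3 counts. Intervals of counts, and limits, cover counting error only. The depth of 59610963 and 44689404 expected counts made counting error small beside the spread between libraries for most detected genes.

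The procedures were tested on simulated data. For the test between the libraries, run on 11291 genes, all 100 genes changed by 3-fold and all 100 changed by 4-fold were called, with 0 calls among 11091 unchanged genes. The simulated counts for that test carried counting noise only, and the changed genes had at least 100 counts. The result therefore says nothing on calls under the larger spread of the real pair. A simulated coefficient of variation of 0.3 was recovered as 0.297 over 10375 genes. Of 200 random lists of 12 genes among 21474, 5 lay above the 97.5th percentile. A simulated GC trend over 8596 genes left a residual SD of 0.300, where the noise put in was 0.3. Alternatives covered other scalings, filters, pseudocounts, estimates, backgrounds and the omission of each library. The software was Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.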

Results

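G1E-ER4 is an erythroid line that lacks its own functional Gata1 and carries a Gata1 protein fused to an estrogen receptor domain, so that estradiol switches Gata1 activity on. The series profiled polyA RNA after 7 hours of 10 nM estradiol, in 2 libraries of 1 group. Replicate 1 held 59610963 expected counts and replicate 2 held 44689404. The question open to these data is which genes the treated cells expressed and how well the libraries repeated each other. No change with estradiol was measured, because no untreated sample was part of the series.

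The cells expressed adult globin genes at high levels and almost no embryonic globin. The beta-globin gene Hbb-bs (chromosome 7, 103826534 to 103828096, GRCm38) stood at a TPM of 9213 ± 3616 (SD, n = 2). The alpha-globin genes Hba-a1 (chromosome 11, 32283511 to 32284465) and Hba-a2 stood at 4967 ± 2271 and 2219 ± 490. Hbb-bt stood at 63.9 ± 56.8. The alpha pair share near-identical sequence, as do Hbb-bs and Hbb-bt, so the split within each pair is uncertain. Alpha over beta adult globin TPM was 0.770 in replicate 1 and 0.784 in replicate 2, a mean of 0.777 ± 0.0099 (SD, n = 2). The Hbb-bs over Hbb-bt ratio was 113 and 280. Hba-x, Hbb-bh1 and Hbb-y, the embryonic globins, summed to 2 counts in replicate 1 (95% exact Poisson interval 0.242 to 7.22) against 402922 counts of adult globin. In replicate 2 they had 0 counts (upper end of the same interval 3.69) against 165712, which is 55237-fold lower if 3 counts are taken as the limit. Embryonic over adult beta-like globin TPM was 7.58e-06 in replicate 1 and 0 in replicate 2. The one theta globin with any count, Hbq1b, had 1 count in replicate 1.

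Genes of heme synthesis were all detected, 12 of 12, with a median TPM of 123, above all of the 10000 random lists (percentile 100). Alad, the second enzyme of the pathway, had a TPM of 483 ± 107, the mitochondrial protein gene Tmem14c 414 ± 157 and the transporter gene Abcb10 246 ± 29.1 (SD, n = 2). Alas2, the erythroid form of the first enzyme, was much lower, at 6.23 ± 4.37. Its TPM of 9.32 and 3.14 depended on isoform assignment, since the transcript Alas2-204 took 70.0% of the gene's TPM in replicate 1 and 0.955% in replicate 2 (34.4% and 0.250% by expected counts). The 12 iron handling genes were also all detected, with a median of 27.8 (percentile 99.6). The ferritin subunit genes Fth1 and Ftl1 led them at 19272 ± 3233 and 12064 ± 1538, followed by Pcbp1 at 1947 ± 694. The transferrin receptor gene Tfrc stood at 21.8 ± 5.73. The iron list fell to the 82.8th percentile against random lists drawn from genes with a TPM of at least 0.1, where the heme list lay at 99.94. The housekeeping list, with a median of 169, lay at percentile 100, and at 99.98 against that background. A high percentile is thus not particular to erythroid genes.

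Of 15 erythroid regulators, 14 were detected, with a median TPM of 262 (percentile 100). Zfpm1, the Gata1 cofactor, was at 2463 ± 686, Klf1 at 1189 ± 290, Lmo2 at 1166 ± 379, Gata1 at 1061 ± 268 and Tal1 at 161 ± 18.5 (SD, n = 2). Gata1 lies on chromosome X (7959260 to 7978071). Its transcript signal here includes any transcript of the introduced fusion that matches Gata1, because the tables did not separate the fusion from the endogenous gene. Gata2, which acts in stem and progenitor cells, stood at 453 ± 118. The ratio of Gata1 to Gata2 TPM was 3.38 in replicate 1 and 1.63 in replicate 2, a mean of 2.51 ± 1.24. By expected counts that ratio was 1.92 and 0.927, so the side of 1 on which replicate 2 fell changed with the unit.

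Membrane and late maturation genes were uneven. Of 18 membrane genes, 14 were detected, with a median TPM of 17.5 (percentile 99.7). Among them the spectrin gene Sptb had 329 ± 15.2, the ankyrin gene Ank1 199 ± 1.43 and Ermap 77.8 ± 25.9 (SD, n = 2). Slc4a1, the anion exchanger of the red cell membrane, was below a TPM of 1 at 0.440 ± 0.113. The authors' interval for its TPM ran from 0.582 to 1.81 in replicate 1 and from 0.452 to 1.99 in replicate 2. Both reach above 1, so a TPM above 1 is not ruled out for Slc4a1. Against random lists from genes with a TPM of at least 0.1, the membrane list lay at the 63.9th percentile. Of 14 matched maturation genes, 11 were detected, with a median of 35.5 (percentile 99.96, and 92.5 against genes with a TPM of at least 0.1). The carbonic anhydrase genes Car2 and Car1 had 409 ± 16.5 and 218 ± 10.4, and catalase, Cat, 163 ± 1.47. By counts Cat had a log2 ratio of replicate 2 over replicate 1 of -0.61, so its small SD holds for TPM only.

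Cytokine signalling and cell cycle genes were mostly detected. Epor, the erythropoietin receptor gene, had a TPM of 168 ± 21.8 and Kit, the stem cell factor receptor gene, 37.0 ± 6.17, a Kit over Epor ratio of 0.219 ± 0.0082 by TPM and 0.646 ± 0.0301 by expected counts (SD, n = 2). The survival gene Mcl1 had 522 ± 198 and the receptor subunit gene Csf2rb 270 ± 84.0, and 13 of 14 genes on this list were detected. All 15 G1 and S phase genes were detected. Their highest means were those of Rrm2 at 371 ± 129, Ccne1 at 310 ± 158 and Mcm2 at 295 ± 25.3, and Ccne1 was above Rrm2 in replicate 2, at 421 against 280. All 13 G2 and M phase genes were detected, led by Cdc20 at 425 ± 38.5, Ube2c at 298 ± 17.5 and Aurkb at 289 ± 28.3. Of 10 cyclin-dependent kinase inhibitors and D cyclins 6 were detected and 2 had 0 counts. Ccnd3 had 656 ± 48.3, Cdkn1a 106 ± 13.6 and Cdkn2c 87.9 ± 10.4. That list and the G2 and M phase list lay at the 99.9th percentile each, and at 93.2 and 93.1 against genes with a TPM of at least 0.1. Among stress genes Egr1 had 181 ± 49.4 and Hspa5 109 ± 15.9, while Hsp90aa1 had 219 in replicate 1 and 32.4 in replicate 2.

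**Figure D1:**
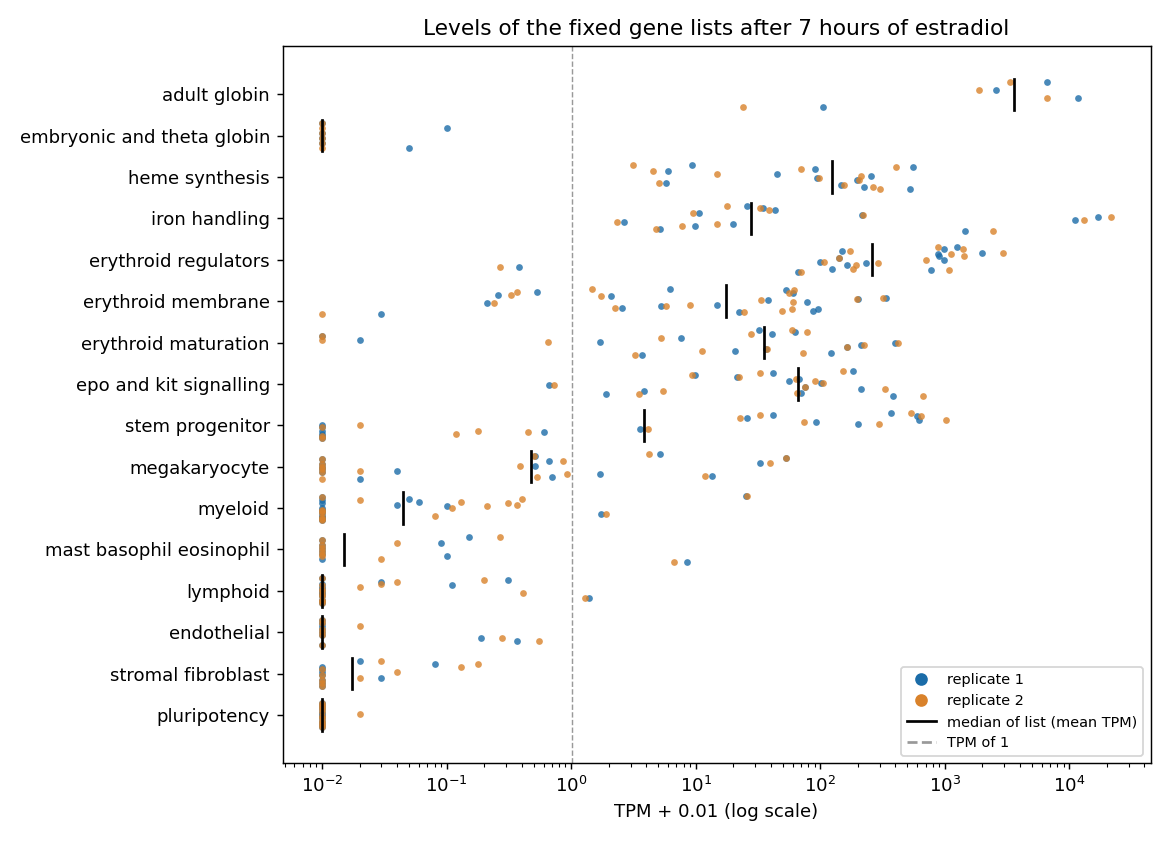
Each point is a gene of a fixed list in 1 library (blue, replicate 1; orange, replicate 2), on a log axis of TPM with 0.01 added; black bars are list medians of the mean TPM and the dashed line marks a TPM of 1. Adult globin, with a median of 3593, heme synthesis, at 123, and the regulators, at 262, have medians to the right of the line, while most markers of other cell types lie to its left.

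Progenitor genes were split. Of 15 stem and progenitor genes 8 were detected, with a median TPM of 3.83 (percentile 92.0, and 3.61 against genes with a TPM of at least 0.1). The second background leaves out silent genes while the list kept its own, so its lower value follows in part from that mismatch. Hhex stood at 818 ± 280 and Myc at 617 ± 32.4 (SD, n = 2). Markers of 7 other cell types were mostly not detected at this depth. Of 89 such genes, 47 had 0 counts in both libraries and 8 had a TPM of at least 1 in both. Those were the megakaryocyte genes Gp1ba at 52.6 ± 0.0778, Gp5 at 36.1 ± 4.96, Fli1 at 12.7 ± 1.18 and Itga2b at 4.67 ± 0.644, the myeloid genes Spi1 at 25.5 ± 0.226 and Cd68 at 1.82 ± 0.120, the mast cell and basophil gene Hdc at 7.63 ± 1.25, and the lymphoid gene Lck at 1.33 ± 0.0849. The highest mean TPM of any other marker was 1.30. None of the pluripotency, endothelial or stromal markers was detected. Among the pluripotency genes Esrrb had 0 and 1 counts and Pou5f1 and Sox2 had 0 counts. Eng had a TPM of 0.450 ± 0.127, Sox17 0.225 ± 0.0636, Col1a2 0.120 ± 0.0707 and Col3a1 0.060 ± 0.0849. Cpa3 of mast cells had 0.200 ± 0.0849, and the lymphoid genes Cd79a and Cd3g had 0.245 ± 0.0778 and 0.200 ± 0.283. Esr1, the estrogen receptor gene, had 0 and 1 counts, and none of the 6 estrogen receptor and target genes reached a TPM of 1.

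**Figure D2:**
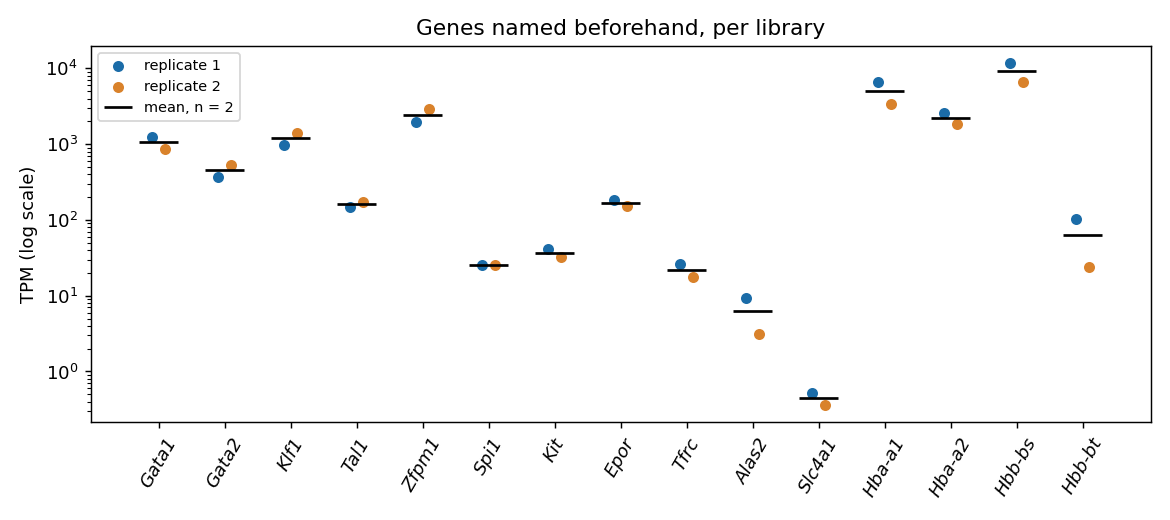
TPM on a log axis for 15 genes chosen before the data were examined; blue points are replicate 1, orange points replicate 2 and bars the mean (n = 2). Globin genes and Gata1 were higher in replicate 1, and Klf1, Zfpm1 and Gata2 were higher in replicate 2.

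The libraries detected 8219 protein-coding genes in common, 38.3% of those measured, with 340 more in replicate 1 alone and 88 in replicate 2 alone. The nuclear protein-coding genes with the highest mean TPM were Rplp1 at 31549 ± 2512, Ptma at 22526 ± 3474, Rpl18 at 19651 ± 835, Fth1, Hist1h2ap at 13403 ± 2597, Ftl1, Rpl28 at 11407 ± 1098, Gapdh at 10447 ± 8989, Hbb-bs and Rpl27a at 8479 ± 1769 (SD, n = 2). Ribosomal protein genes took 6.07% ± 1.57 of expected counts, replication-dependent histone genes 0.823% ± 0.0836, adult globins 0.523% ± 0.216 and mitochondrial genes 0.297% ± 0.0758. The 10 most abundant genes by count took 11.6% ± 1.90. Of these, the non-coding genes Gm26917 and Gm42418 together took 5.66% ± 2.12 of all counts. The 5 matched small RNAs without a polyA tail took 0.0108% ± 0.0024, a share that does not measure all RNA without a tail. Of them, Rn7sk had a TPM of 493 ± 13.1, Rpph1 155 ± 105 and Rmrp 131 ± 117.

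Between the libraries, the medians of 4 lists with roles in red cell production or division were lower in replicate 2 than those of random lists, though members went both ways in 3 of them. The median log2 ratio of replicate 2 over replicate 1 was -0.73 for adult globin (percentile 0.280 of random lists), -0.40 for G2 and M phase (0.330), -0.31 for maturation (1.65) and -0.23 for heme synthesis (2.29). From TPM in place of counts, the maturation list lay at percentile 31.3 and the heme list at 2.89, inside the range of random lists, while the housekeeping list, at 8.94 from counts, lay outside it at 1.16 with a median of -0.51. Single genes called different numbered 0 of 12 in the heme list, 1 of 14 in the maturation list, 4 of 13 in the G2 and M phase list and 1 of 4 adult globins. Abcb10 had a log2 ratio of 0.35, Car2 0.45 and Cdc20 0.30. The maturation list also moved to percentile 3.34 once a GC trend was removed. The myeloid list was higher in replicate 2, with a median log2 ratio of 1.73 (99.99th percentile) over 6 members. Of its 17 genes 3 were called, all higher in replicate 2. Its shift came from small counts, with Cebpe at 2 counts in replicate 1 and 15 in replicate 2, while Spi1 had a log2 ratio of 0.05. Erythroid regulators had a median of 0.33 and lay inside the range of random lists (percentile 71.2). Housekeeping genes were not level either, since Gapdh had a log2 ratio of -1.18 and Actb -1.27, against 0.09 for Rpl13a.

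**Figure D3:**
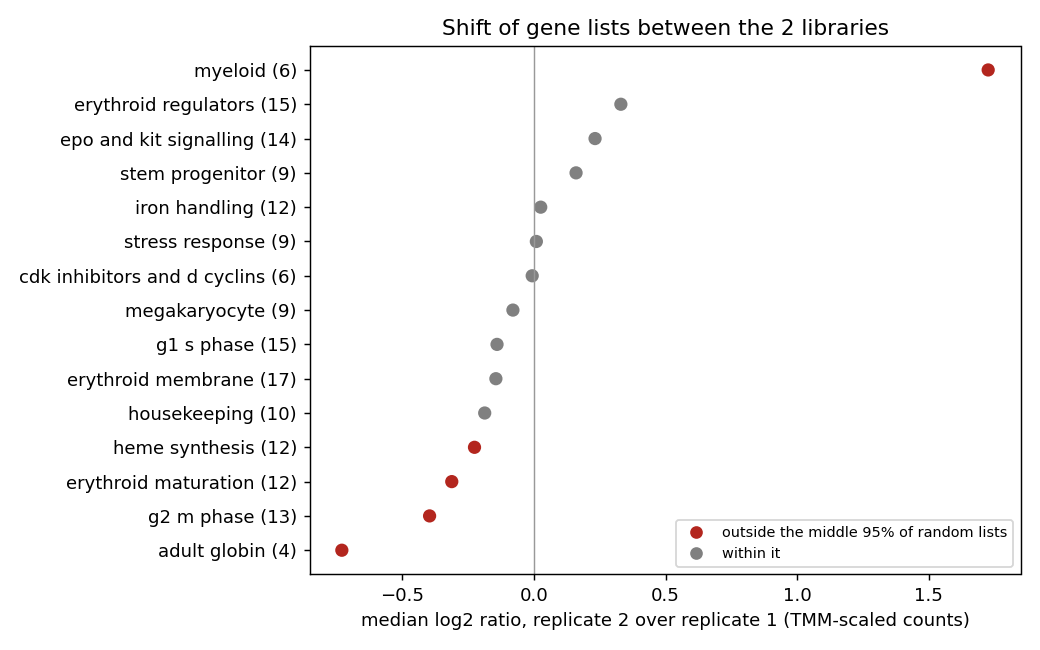
Median log2 ratio of replicate 2 over replicate 1 for each list with at least 3 members of 10 counts or more, the number of members in brackets; red points lie outside the middle 95% of random lists matched on expression. Adult globin at -0.73 is the lowest and the myeloid list at 1.73 the highest.

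Across protein-coding genes Pearson's r of log2 TPM was 0.990 and Spearman's rho 0.952. Among detected genes the median SD was 17.6% of the mean, and 70.8% lay within 1.5 times between the libraries. The biological coefficient of variation was 0.287 by edgeR. Of 11291 genes tested, 1261 were called different by the exact binomial test, 945 higher in replicate 1 and 316 higher in replicate 2. When the spread of the pair itself was allowed for, 103 were called. That spread was estimated from the same 2 libraries, so this count is a description and not an independent test. The chi-square of the counts was 292 per degree of freedom, so the libraries were not 1 library deposited again.

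Among genes called different at a mean TPM of at least 5, the 10 largest log2 ratios were mostly those of processed pseudogenes. Reads of these can be shared with their parent genes, and their values are uncertain. Gm10231 (-10.17), Gm10132 (-9.76), Gm14760 (-9.21), Gm15710 (-8.36), Gm11518 (-7.65), Rpl15-ps3 (-6.63) and Gm10259 (-5.05) were lower in replicate 2, and Gm12751 (9.81) was higher. The other members were mt-Co2 (-8.51) and the histone gene Hist3h2a (-4.90), which also have close copies. Ratios with a count of 0 on one side depend on the prior count and give no fold.

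Transcript shares within a gene were compared for 18 genes, mainly by the leading transcript. Gata1-201 held nearly all of Gata1 TPM, a signal that includes any transcript of the introduced fusion that matches Gata1. Zfpm1-201 held 99.0% ± 0.544, Alad-201 94.3% ± 0.385, Runx1-203 92.8% ± 1.86, Myb-203 91.7% ± 2.97, Gata2-201 90.4% ± 4.03, Bcl2l1-201 88.6% ± 12.8 and Kit-201 87.0% ± 2.94 (SD, n = 2). Klf1 and Epor each had a single annotated transcript, and Slc4a1-201 held 39.5% of the low Slc4a1 signal by posterior mean TPM but all of it by TPM. Tal1-204 held 69.2% ± 4.93, Epb41-215 66.7% ± 4.32 and Ank1-207 46.6% ± 1.72. Lmo2-206 held 36.6% in replicate 1 and 71.1% in replicate 2 by TPM, and 20.5% and 50.3% by expected counts. Lesser transcripts also moved between replicates 1 and 2 by TPM, with Epb41-213 at 4.62% and 24.8%, Ank1-201 at 15.7% and 3.24%, Bcl2l1-209 at 11.7% and 0.0935% and Lmo2-207 at 28.4% and 7.87%. By expected counts Epb41-213 held 2.16% and 13.0%, Ank1-201 2.43% and 0.461%, Bcl2l1-209 4.52% and 0.0327% and Lmo2-207 27.4% and 9.43%. The short Pklr-205 held 73.2% ± 3.72 of Pklr by TPM and 18.6% by expected counts, so its rank depended on the unit.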

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

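Tests written only after the related values had been seen were those of a further matured culture, of reads shared between near-identical copies, of a complete loss over the GC range of the Y-linked genes (its bound of 100 genes was set with counts near those genes known), of removed mitochondrial reads and of the nuclear copy of mitochondrial genes. The count of genes called after GC correction, and the reading of each maturity list by itself, were also added after the first values of those tests were seen. The other tests were written before the value they measure was seen, but the mitochondrial GC test was set aside and taken up again after other mitochondrial values were known. The biological explanations tested were the maturity of the cultures and the lack of a transcribed Y chromosome, and no other was tested, since the design holds 1 group.

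Gene levels differed between the libraries by more than counting noise. Over 8596 protein-coding genes with at least 50 counts in each library, that noise gave 2.72% of the variance of the log2 ratio. A smooth curve on GC content removed 7.09% of that variance, between the bounds of 5% and 25% set beforehand, and 1131 genes were called with the trend removed, so GC was not the whole cause; effective length removed 3.28% of the rest. Pseudogenes made up 11.4% of the called genes, so most calls were of other genes. That share does not measure reads shared between copies, its value among all tested genes is not given, and coding genes with close copies were not counted. Whether shared copies were the main cause is thus not decided. Replicate 1 may have been further matured: the adult globin, heme and membrane lists together lay at percentile 0.120 after GC correction, but the globin and heme shifts had prompted that test and the membrane list alone lay at percentile 27.6. The maturation list, at 3.34, and the G2 and M phase list, at 1.48, were not part of that test and were also lower in replicate 2. A lower maturation list is what further maturation of replicate 1 would give, so it does not speak against that explanation. The G2 and M phase list holds genes of dividing cells, so such a shift was not limited to lists of red cell genes. Further maturation of replicate 1 stays open, as does any difference in library preparation, on which the labels are silent. A difference in maturity would need separate cultures, and both libraries cited the same biological sample record.

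The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both libraries, although the labels give the line as male. The summed count of all 183 Y-linked protein-coding genes was 0 in each library, so the cells may lack a transcribed Y chromosome. Their X-linked partners had at least 1012 counts. A complete loss over their GC range is argued against by 414 of 2393 other nuclear genes in that range with more than 100 counts in each library. A lower yield stays open. The share of such genes within 1 point of GC was 24.2% around Kdm5d but 6.94% around Ddx3y. That share also depends on which genes the cells express, so it does not measure yield. The partners differed in GC by 4.07 to 12.9 points.

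Mitochondrial messenger RNAs took 0.340% of counts in replicate 1 and 0.239% in replicate 2, and no reference level was at hand to say how low that is. Removal of mitochondrial reads before deposit is argued against by 9 of 13 messenger RNAs with more than 100 counts in each library. The 6 pseudogenes of a nuclear copy on chromosome 1 held a mean of 23.1% of the counts of both together, 27.9% and 18.2% by library; with it added, the shares were 0.472% and 0.293%, so it could account for a part only. For GC bias, the mitochondrial median log2 ratio lay 0.0498 SD from nuclear genes of like GC, but the members ranged from -8.51 to 3.54, so the median decides nothing. Nuclear genes at or below the mitochondrial median GC were detected in 4.31% of cases against 38.8% of the others. Those shares also depend on which genes the cells express, so they do not measure yield. A low yield of such transcripts stays open.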

How the results depend on the processing

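Alternatives chosen after seeing the data were the GC correction, the restriction to protein-coding genes and the GC-matched random lists. No paired analysis was possible because the series has 1 group. No list shift that lay outside random lists changed sign under the alternatives run; of shifts inside them, the iron list went from 0.03 to -0.13 with TPM, the list of kinase inhibitors and D cyclins from -0.01 to 0.01 with DESeq2 size factors and the megakaryocyte list from -0.08 to 0.01 with the GC curve removed. Genes detected ranged from 6241 at a TPM of at least 5 to 9724 at 0.1. Pearson's r was 0.992 with a pseudocount of 0.1, 0.968 among detected genes and 0.992 on TMM-scaled counts, and Spearman's rho among detected genes was 0.964. The coefficient of variation was 0.298 with no filter and 0.161 as the DESeq2 gene-wise median. Genes called different numbered 103 with the pair's own dispersion allowed for, and 1004 to 1605 under the others. Total-count scaling shifted every log2 ratio by -0.21 and put 89.6% of calls higher in replicate 1, against 74.9% with TMM. Lists above the upper limit of random lists numbered 6 against genes with a TPM of at least 0.1, and 11 of 23 otherwise. The background of at least 0.1 leaves out silent genes while the lists keep theirs, so a list with many silent members falls by construction. Against that background the stem and progenitor list lay at percentile 3.61 and the megakaryocyte list at 0, from 92.0 and 69.9. Lists with a shift outside random lists numbered 4 or 5. Of 18 leading transcript shares, 7 moved past their SD by expected counts and 4 by posterior mean TPM. By expected counts, alpha over beta globin was 0.712 and Kit over Epor 0.646. By posterior mean TPM, embryonic over adult beta globin was 1.57e-05, a value set by the prior where counts are 0. As shares of TPM, mitochondrial genes held 0.555%, their messenger RNAs 0.546%, ribosomal protein genes 17.1%, histone genes 3.14%, adult globins 1.65%, small RNAs 0.0779%, Gm26917 and Gm42418 3.10%, pseudogenes 2.37% and the 10 most abundant genes 15.2%; TPM weighs short transcripts more. Other causes were not tested. With 2 libraries, leaving 1 out cannot move a mean past its SD, and says nothing on stability. Markers with under 3 counts could not be told from 0.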

Other observations

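Granulocyte genes had small counts that differed between the libraries, which was noticed after the data were examined and not tested further. Mpo had 0 counts in replicate 1 and 24 in replicate 2, Elane 1 and 10, Prtn3 3 and 6 and Ctsg 0 and 3. Lyz2, S100a8, S100a9 and Ltf had 0 counts in both libraries.

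Tsix, which is antisense to Xist, had a TPM of 6.35 ± 0.346 (SD, n = 2), while Xist had 3 and 1 counts. The sources used here do not state whether counting used strand, so reads of the overlapping pair cannot be assigned with certainty.

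Detection differed with GC content. Of protein-coding genes under 40% GC, 13.2% were detected in both libraries, and of those between 55% and 60% GC, 48.3% were, while above 60% GC the share was 41.4%. These shares also depend on which genes the cells express. The median log2 ratio of replicate 2 over replicate 1 went from -0.24 in the lowest GC class to 0.45 in genes above 60% GC.

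The non-coding genes Gm26917 and Gm42418, neighbours on chromosome 17, were singled out after their values were seen. They had at least 1635686 and 843095 counts in each library, and together took 4.16% of counts in replicate 1 and 7.16% in replicate 2. Gm26917 was called different, with a log2 ratio of 1.09, and Gm42418, at 0.78, was not. The nuclear copy of mitochondrial genes lies on chromosome 1 (24612407 to 24616197), and its 6 pseudogenes had summed counts of 78562 in replicate 1 and 23851 in replicate 2.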
